A study of Homo sapiens with 6 samples.

How the data were processed

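The series holds 6 Illumina expression BeadChip arrays of 2 human prostate cancer cell lines, with 1 array in each of 6 groups and no replicates. LNCaP is an androgen-responsive line, and LNCaP-abl is a derivative that was established by long culture without androgen. Per the labels, both lines received either 1 nM R1881, a synthetic androgen, or its ethanol vehicle for 48 h, and LNCaP cells also received either a non-targeting siRNA or an siRNA against EZH2. Time after transfection was not given in the sources used here. Sample titles describe the LNCaP vehicle and R1881 cultures as hormone deprived, whereas their source descriptions give 10% fetal calf serum for 2 days before treatment, and this conflict was left open. Serum was also at 10% in the LNCaP-abl and siRNA cultures. Per the labels, total RNA was extracted with Trizol and biotin-labelled cRNA was made with the Ambion MessageAmp kit.

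Each array's signal was deposited as a linear intensity per probe, together with its standard error over beads, the number of beads and a detection p-value, per the file headers. Intensities were made with GenomeStudio, per the submitters' processing notes, and its version was not given in the sources used here. In the deposited intensities 25.1% to 27.5% of probes lay below 0 and probes at mid detection lay near 0, so a background had already been subtracted, and the quartiles differed between arrays. The deposited detection p-value fell with the intensity, from 1 to 0. A further deposited table gave log2 values of the same 6 arrays, with column medians of 6.925 on 5 arrays and 6.924 on the EZH2 siRNA array. Those log2 values ranked probes nearly as the intensities did, had the same lower and upper quartiles on all arrays and, once unlogged, kept an intercept of 111 to 112 intensity units. How they were normalised and why the intercept was kept was not given in the sources used here, so they served only as an alternative. No genome build was given for the probe coordinates, so chromosomes and cytobands are named without positions.

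Values used here were computed from the deposited intensities of 47220 probes, after 93 control probes had been left out. The neqc function of limma 3.58.1 in R 4.3.3 was run on all 6 arrays together. It fitted a normal-exponential background from the detection p-values, added an offset of 16, quantile normalised and took log2. Symbols were brought up to date through the Entrez ID for 35665 probes and through the accession for 84 probes, while 8203 kept the symbol of the file and 3268 had none. For 8832 probes the symbol became a newer one. Each of 30465 genes was represented by its brightest probe over the 6 arrays, which was a choice among several probes for 8906 genes.

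With 1 array per group no test between conditions was possible, and no p-value is given across genes. A gene counted as measured in a comparison when its detection p was under 0.01 on at least 1 of the arrays compared, and as higher or lower when the difference was at least 1.5-fold. The error given is the bead standard error (SE), which was carried to the log2 scale and combined over the arrays. It covers measurement on these arrays, not differences between cultures. Where the dimmer array was not above background on any probe of the gene, only a bound is given. The bound sets the bright array's normalised value against the higher of the dim probe's value and the lowest value of any detected probe on the dim array. Differences of 3 genes whose used probe was at background while another probe was detected are given no bound. A list median is also given with such members at their bounds where this altered the printed value, by at most 0.442. This was not done for the difference of responses. Counts of higher and lower genes include genes whose bound is under 1.5-fold, and percentiles belong to the medians without bounds.

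A total of 21 gene lists with 581 entries, all matched to the array, were fixed before the data were examined, as were the groups, the comparisons, the size threshold, the rule for naming genes and most alternatives. The lists held androgen-induced and androgen-repressed genes, subunits of Polycomb repressive complexes 1 and 2 (PRC1 and PRC2), genes reported as repressed by EZH2, developmental transcription factors bound by Polycomb, and genes of G1/S and DNA replication. Others held genes of G2/M and mitosis, cell-cycle inhibitors and p53 targets, cholesterol and fatty acid synthesis, steroid and glucuronide metabolism, the unfolded protein and amino acid stress response, interferon-stimulated genes, and hypoxia and glycolysis. The rest held luminal, basal, neuroendocrine, mesenchymal, and blood and endothelial markers, and ribosomal and housekeeping genes. The result of 1 further list is not given here. Lists came from general knowledge and share some members. The androgen-induced and luminal lists share 4 genes including KLK2, KLK3 and KRT19, and the androgen-repressed and steroid lists share 6 genes including UGT2B10, UGT2B11, UGT2B15 and UGT2B17. The inhibitor list and the EZH2-repressed list share CDKN1A, CDKN1C, CDKN2A and CDKN2B.

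For each list with at least 3 measured members, the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these arrays and is no test. Random lists kept their values without bounds. A median with bounds that lies within the central 95% is therefore set beside an interval not shrunk likewise, and does not show that the shift is absent. Of 100 pairs of a list and a comparison, 46 lay outside the central 95% of random lists. Overlaps of higher and lower genes between 2 comparisons without a shared array were set beside the product expected of independent lists and beside 10000 draws matched on expression. Named in each comparison were the 10 genes with the largest difference in each direction that had an official-style symbol, up to 4 members of each list, and always a fixed set including EZH2, KLK3, TMPRSS2 and FKBP5. Not every gene that met this rule is printed. For overlaps, the 10 genes with the largest smaller difference were eligible.

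The steps were tested on simulated data made from the LNCaP vehicle array with its bead noise. In the simulated R1881 comparison of 47220 probes, 50 of 50 probes raised 4-fold and 45 of 50 raised 2-fold were called higher, and 43 of 50 halved probes and 49 of 49 quartered probes were called lower. Among 15216 unchanged probes, 0.96% were called higher and 1.10% lower. The median difference recovered for 2-fold raised probes was 0.91 on the log2 scale, so sizes were understated. Of 200 random lists of 25 genes, 5.5% fell outside the central interval, and 98.5% did after a shift of 0.5. For calls in the R1881 comparison set against permuted calls of the siRNA comparison, 7 of 100 overlaps fell outside.

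Alternatives were another background correction, another normalisation (median scaling, cyclic loess, or each BeadChip alone), the deposited log2 values, the mean of detected probes, other detection filters and other size thresholds. The 4 LNCaP arrays lay on 1 BeadChip and both LNCaP-abl arrays on another, so cell line and chip cannot be told apart, while each treatment comparison lay within a chip. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Current symbols came from a RefSeq gene table of the GRCh38.p14 assembly.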

Results

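Gene expression was measured on 6 arrays, 1 per group, in LNCaP and LNCaP-abl prostate cancer cells. The design text and title pose how expression depends on cell line, on androgen and on EZH2, the catalytic subunit of the Polycomb complex PRC2. Detected probes at p under 0.01 numbered 14079 in LNCaP with vehicle, 13624 with R1881, 12649 with control siRNA and 14257 with EZH2 siRNA. In LNCaP-abl they numbered 15251 with vehicle and 16287 with R1881. Normalised values correlated across probes at 0.989 between the LNCaP-abl arrays, from 0.958 to 0.974 among the LNCaP arrays and from 0.888 to 0.906 between lines. Because there were no replicates, each difference compares 2 arrays and has no replicate check. A probe was read from a median of 22 or 23 beads per array, and over all detected probes the median bead SE was 7% to 8% of the signal.

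EZH2, on chromosome 7q36.1a, was 2.48-fold lower with EZH2 siRNA than with control siRNA, a log2 difference of -1.31 with a bead SE of 0.19. The intensity of the probe used was 155.8 with control siRNA and 62.7 with EZH2 siRNA. The other 2 probes for EZH2 gave -1.19 and -1.88, the latter with the EZH2 siRNA array not above background. EZH2 intensity was 97.4 in LNCaP with vehicle and 57.7 with R1881, a log2 difference of -0.67 (bead SE 0.17). The other EZH2 probes gave -0.39 and -0.55 there, the latter with the R1881 array not above background. In LNCaP-abl EZH2 intensity was 98.2 with vehicle and 117.8 with R1881, a log2 difference of 0.17 (bead SE 0.17).

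**Figure D1:**
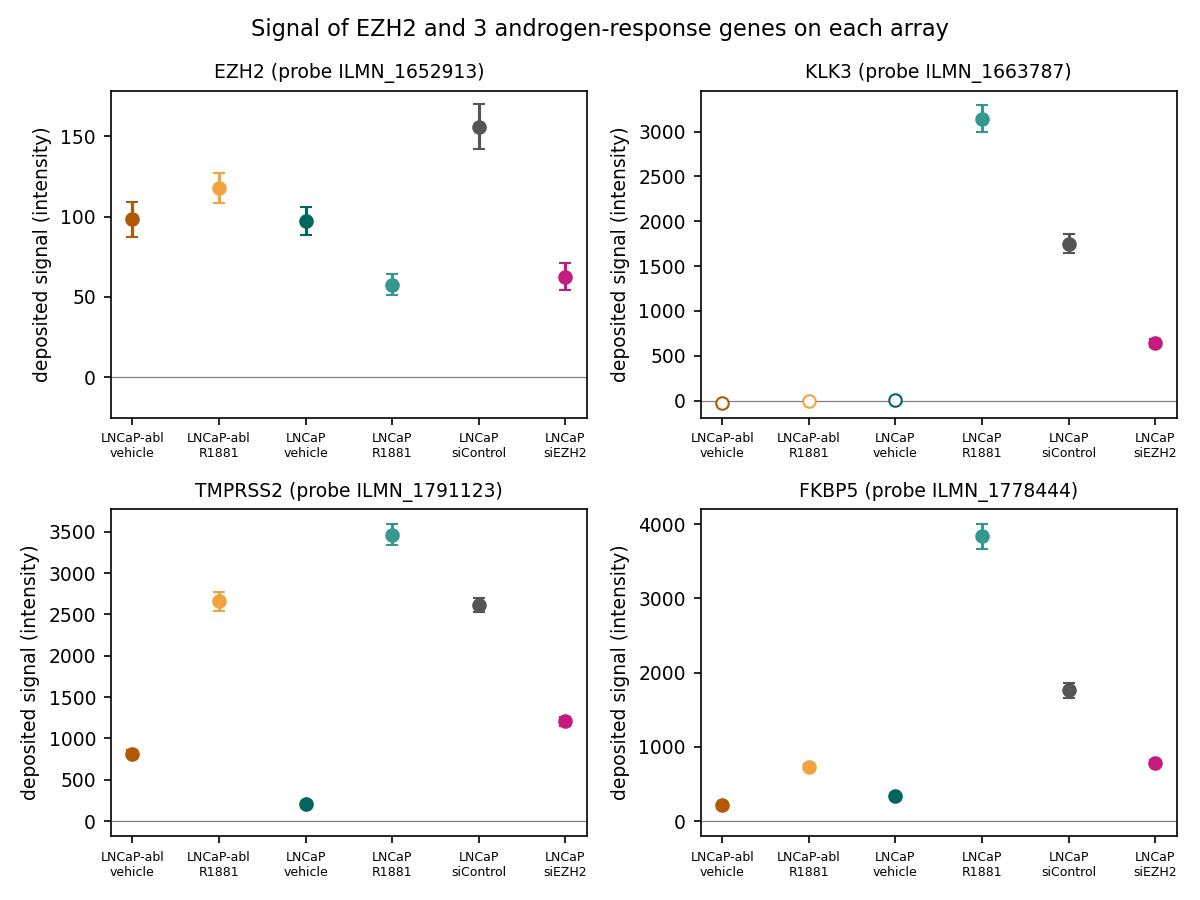
Deposited intensity of the probe used for EZH2, KLK3, TMPRSS2 and FKBP5 (vertical axes) on each of the 6 arrays (horizontal axes), with bars for the bead SE and open circles where the probe was not above background. EZH2 was at 155.8 with control siRNA and 62.7 with EZH2 siRNA, and KLK3 was not above background on this probe in LNCaP with vehicle or on either LNCaP-abl array.

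With R1881 in LNCaP, the classical androgen targets were much higher than with vehicle, in cultures labelled both as hormone deprived and as grown in 10% serum. KLK3 on 19q13.33c, which encodes prostate-specific antigen, was at least 56.1-fold higher on its brightest probe. The intensity of that probe was 5.7 with vehicle, not above background, and 3142.5 with R1881. Another KLK3 probe gave a smaller log2 difference of 3.24, from 20.4 with vehicle, also not above background, to 355.1 with R1881. The remaining KLK3 probe was not above background with either treatment. TMPRSS2 on 21q22.3a, a membrane serine protease gene, was 13.8-fold higher (log2 3.79, bead SE 0.12), and FKBP5, an immunophilin co-chaperone, 9.44-fold higher (3.24, 0.16). Of 38 measured androgen-induced genes, 36 were at least 1.5-fold higher, 0 were lower and 2 were under the threshold, with a median log2 difference of 2.49, or 2.37 with members at background set to their bounds, at percentile 100 of matched random lists. Of 20 measured androgen-repressed genes, 13 were lower, 3 higher and 4 under the threshold, with a median of -0.94 at percentile 0.

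Other genes not above background with vehicle were GNMT, glycine N-methyltransferase, at least 34.3-fold higher, and KRT6B, an epithelial keratin, at least 23.6-fold higher. ZNF812P was at least 15.1-fold higher, TUBA3E, an alpha tubulin, at least 8.92-fold and HPGD, which inactivates prostaglandins, at least 7.23-fold. MAF, a leucine zipper transcription factor, was 19.3-fold higher, the calcium-binding S100P 17.7-fold and TRIM51 16.1-fold. NDRG1, a stress-responsive gene, had an intensity of 355.9 with vehicle and 6882.3 with R1881. At the other end, DDC, the decarboxylase that makes dopamine and serotonin, was 52.1-fold lower (log2 -5.70, bead SE 0.19). BCHE, butyrylcholinesterase, was 19.9-fold lower, CAMK2N1, an inhibitor of calmodulin kinase II, 18.3-fold lower and BARD1, the partner of BRCA1, 8.91-fold lower. GRB10, an adaptor of insulin signalling, was 8.67-fold lower, the hormone gene RLN2 7.43-fold and UGT2B17, which glucuronidates androgens, 7.05-fold. CBLN2 was at least 6.19-fold, ID3, an inhibitor of helix-loop-helix factors, at least 6.02-fold and VWF, von Willebrand factor, at least 5.75-fold lower. Probes for KRT6B, TUBA3E, RLN2 and the UGT2B genes may cross-hybridise with close paralogs.

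Genes of cholesterol and fatty acid synthesis were mostly higher with R1881 in LNCaP, with 26 of 31 higher, 1 lower and a median of 1.10, or 1.06 with bounds, at percentile 100. Among them were ELOVL5, a fatty acid elongase (2.25), and CYP51A1, a sterol demethylase (1.74). Proliferation genes were lower. Of 28 measured genes of G1/S and DNA replication, 15 were lower and 0 higher (median -0.61, or -0.56 with bounds, percentile 0), including CCNE2, a cyclin (-1.58), and the helicase subunits MCM2 (-1.28) and MCM7 (-1.16). Of 28 genes of G2/M and mitosis, 13 were lower and 0 higher (median -0.56, percentile 0), including CDK1 (-1.02) and TOP2A (-0.99). Hypoxia and glycolysis genes were higher in 11 of 23 and lower in 2 (median 0.49, percentile 100), with the glucose transporter SLC2A3 at least 3.98-fold higher. Stress response genes were higher in 9 of 24 and lower in 4 (0.35, percentile 99.99), with ATF3 at 1.86 and PDIA5, a disulfide isomerase, at 1.73.

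PRC2 subunits had 1 of 9 members higher and 2 lower with R1881 in LNCaP (median -0.17, percentile 27.0), namely RBBP7 (0.68), JARID2 (-0.82) and EZH2. PRC1 subunits had 4 of 9 lower and 0 higher (-0.44, percentile 1.57), with CBX2 at -1.30 and CBX6 at -1.02. Developmental transcription factors bound by Polycomb had 8 of 19 lower and 5 higher (-0.42, percentile 0.47), with IRX3 at -1.87 and GATA2, a zinc finger factor, at -1.53. Without a detection filter that list's median was 0.01. Genes reported as repressed by EZH2 had 4 of 14 higher and 3 lower (-0.30, or -0.05 with bounds, percentile 6.09), and CDKN2B, an inhibitor of CDK4 and CDK6, was at least 7.08-fold higher. Luminal markers were higher in 8 of 17 and lower in 3 (0.36, percentile 99.8). Neuroendocrine markers were lower in 3 of 5 and higher in 0 (-0.91, percentile 0.12), mesenchymal markers higher in 4 of 7 and lower in 1 (1.05, percentile 99.99), and neither median kept its sign without a detection filter, at 0.05 and -0.01. Within the central 95% lay cell-cycle inhibitors (5 of 17 higher, 3 lower, median -0.27), steroid metabolism (5 of 13 higher, 2 lower, 0.22) and interferon-stimulated genes (4 of 21 higher, 4 lower, -0.01, or 0 with bounds). So did blood and endothelial markers (0 of 3 higher, 1 lower, -0.39, or -0.20 with bounds) and housekeeping genes (2 of 24 higher, 1 lower, -0.02).

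In all, 1265 genes were higher and 1407 lower with R1881 in LNCaP among 11451 measured, and 1238 and 1339 of these differed by more than the bead error allowed at 95%. The higher share was 47.3%, and 57.6% with the deposited log2 values (498 higher, 366 lower). A second detected probe had the same sign for 517 of 563 genes and reached 1.5-fold the same way for 333 of them. With the control siRNA array in place of the vehicle array, a choice made after seeing the data, 478 of the 1265 higher and 264 of the 1407 lower genes were called the same way.

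With R1881 in LNCaP-abl, fewer genes differed, and androgen targets led the higher ones. SLC45A3, the prostate transporter prostein, was 10.3-fold higher (log2 3.36, bead SE 0.12), SGK1, a serum- and glucocorticoid-regulated kinase, 6.65-fold (2.73, 0.10) and KLK4, a kallikrein protease, 6.55-fold (2.71, 0.09). PGC, pepsinogen C, was at least 7.43-fold higher and TRPM8, a cold-sensing ion channel, at least 3.12-fold. MBOAT2, an acyltransferase, was 4.98-fold and CTNNA2, an alpha catenin, 4.84-fold higher. TMPRSS2 was 3.43-fold and FKBP5 3.23-fold higher. KLK3 was not above background on the probe used with either treatment, although another of its probes reached an intensity of 21.3 with R1881 at a detection p of 0.0078. Of 32 measured androgen-induced genes, 27 were higher and 0 lower, with a median of 1.15, or 1.07 with bounds, at percentile 100.

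The MIR1974 probe had the largest negative difference in LNCaP-abl, 5.86-fold lower with R1881. AOC1, diamine oxidase, was 4.09-fold lower, PMP22, a myelin protein gene, 3.74-fold, SCGN, a calcium-binding neuroendocrine marker, 3.07-fold and the homeobox gene HOXA13 2.77-fold lower. RSPH10B, KCNU1, HOXA11-AS, TMEM116 and PCED1B were 2.67-fold, 2.48-fold, 2.38-fold, 2.37-fold and 2.34-fold lower. Androgen-repressed genes were lower in 3 of 18 and higher in 2 (median -0.20, or -0.18 with bounds, percentile 0.17), with UGT2B17 at -1.18 and LIFR, a cytokine receptor, at 1.26.

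Stress response genes were higher in 5 of 27 and lower in 0 with R1881 in LNCaP-abl, and all 27 had a positive difference (median 0.31, percentile 100). CREB3L4, an endoplasmic reticulum transcription factor, was at 1.42, CTH, cystathionine gamma-lyase, at 1.27 and PDIA5 at 1.16. Cholesterol and fatty acid genes were higher in 5 of 31 and lower in 0 (0.23, percentile 100), with FASN, fatty acid synthase, at 0.70. Genes of G2/M and mitosis had 28 of 28 under the threshold, with a median of 0.20 at percentile 99.95, and HMMR was at 0.51. Genes of G1/S had 1 of 29 higher and 0 lower (0.09, percentile 96.6). Polycomb-bound developmental factors had 4 of 26 lower and 0 higher (-0.22, or -0.16 with bounds, percentile 0.06), among them HOXC13 at -0.91. Small negative medians outside the central 95% were found for interferon-stimulated genes (-0.19, 1 of 26 higher and 1 lower), hypoxia and glycolysis (-0.13, 1 of 23 higher and 1 lower), steroid metabolism (-0.19, or -0.16 and within the interval with bounds, 1 of 12 higher and 2 lower) and mesenchymal markers (-0.37, 5 of 5 under the threshold, and 0.09 without a detection filter). PRC2 (0.03) and PRC1 (0.04) had 0 of 10 members each past the threshold. Within the interval also lay EZH2-repressed genes (2 of 12 higher, 1 lower, -0.12), cell-cycle inhibitors (1 of 16 higher, 1 lower, -0.08) and luminal markers (4 of 17 higher, 0 lower, 0.07). Neuroendocrine markers (0 of 6 higher, 2 lower, -0.20) and blood markers (1 of 4 higher, 0 lower, -0.05, or -0.12 with bounds) did too, as did housekeeping genes (-0.04), of which 0 of 24 passed the threshold.

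Across 12474 measured genes, 322 were higher and 287 lower with R1881 in LNCaP-abl. The higher share of 52.9% became 64.9% with median scaling (425 higher, 230 lower). A second probe had the same sign for 147 of 160 genes but reached 1.5-fold the same way for only 63 of them.

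Between lines, the R1881 responses ran the same way for most genes that passed the threshold in both. Of 270 such genes among 10552 measured in both comparisons, 251 had the same sign, with 160 higher and 91 lower in both lines. Independent lists of these sizes would share 28.5 higher and 20.5 lower genes. SLC45A3 (3.44 in LNCaP, 3.36 in LNCaP-abl), KLK4 (2.36, 2.71) and MBOAT2 (2.62, 2.32) were higher in both. UGT2B17, the transcription factor genes ZBTB43 (-1.88, -1.05) and ZBTB34 (-1.07, -1.02), and SELENBP1 (-1.16, -1.17) were lower in both. Across genes, which are not replicates, the differences correlated at a Pearson coefficient of 0.409 and a Spearman coefficient of 0.308.

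The difference of responses, LNCaP-abl minus LNCaP, reached 1.5-fold for 1545 genes in the positive and 1356 in the negative direction among 13373, of which 904 and 789 were detected on all 4 arrays, and it was not tested. Among the 10 genes at each end, those detected on all 4 arrays were TRIM51 on the negative side (-4.08, bead SE 0.18) and DDC (5.04, 0.22), CAMK2N1 (3.75, 0.14), BARD1 (3.10, 0.12), GRB10 (2.71) and RLN2 (2.60) on the positive side. The other 9 at the negative end, KLK3, KRT6B, GNMT, ZNF812P, MAF, ANGPT2, HPGD, TUBA3E and KRT6C, were not above background on either LNCaP-abl array on the probe used, so their response there was not measured and no size is given. BCHE, VWF, CBLN2, LRRC31 and ID3 at the positive end were not above background on at least 1 of the 4 arrays, and no size is given for them either. By list, the median difference was negative for androgen-induced genes (-1.14, with 26 of 40 at least 1.5-fold negative and 2 positive), cholesterol and fatty acid genes (-0.74, 19 of 32 and 1) and hypoxia genes (-0.58, 12 of 24 and 1). It was positive for genes of G2/M (0.76, with 22 of 28 at least 1.5-fold positive and 0 negative), G1/S (0.75, 19 of 30 and 0) and androgen-repressed genes (0.65, 12 of 23 and 3). Over members detected on all 4 arrays the androgen-induced median was -0.64 and the androgen-repressed median 1.23. Basal markers had 3 measured members here and too few in each of the 4 main comparisons, with a median of -1.14 at percentile 0.105 and 2 of 3 at least 1.5-fold negative. The mesenchymal median was -0.66, and 0.07 without a detection filter.

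**Figure D2:**
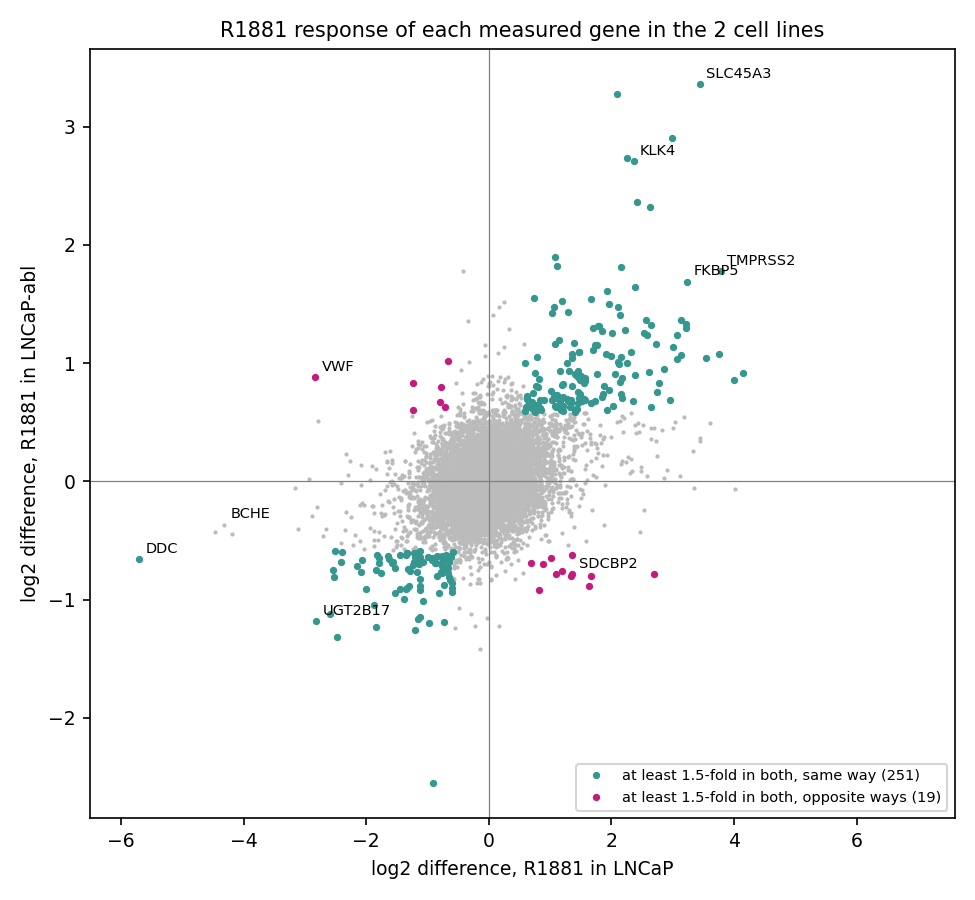
Each point is a gene measured in both R1881 comparisons, with its log2 difference in LNCaP (horizontal axis) and in LNCaP-abl (vertical axis). Green points (251 genes) reached 1.5-fold the same way in both lines, and pink points (19 genes) in opposite ways.

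With EZH2 siRNA in LNCaP, IGFBP3, which binds insulin-like growth factors, was 35.9-fold higher than with control siRNA (log2 5.17, bead SE 0.17). Several UGT2B genes, which encode glucuronosyltransferases, were higher too, with UGT2B15 11.2-fold higher (3.48, 0.13), UGT2B17 8.72-fold (3.12, 0.09), UGT2B11 5.70-fold (2.51, 0.12) and UGT2B10 at least 6.78-fold higher. These are close paralogs whose probes may share signal, and they were low on the control siRNA array, with UGT2B15 at an intensity of 2703.9 with vehicle, 606.1 with R1881, 85.1 with control siRNA and 1388.2 with EZH2 siRNA. IL1RN, the interleukin 1 receptor antagonist, was at least 2.79-fold and CCDC83 at least 2.43-fold higher. The small RNA genes SCARNA13, SNORD3D and SNORA12 were 7.33-fold, 5.83-fold and 5.71-fold higher. ARG2, mitochondrial arginase, was 6.77-fold lower (-2.76, 0.13), PPP1CB, a catalytic subunit of protein phosphatase 1, 4.39-fold lower and TRIM51 4.35-fold lower. SLC39A14, a zinc transporter, was at least 3.68-fold, AZGP1, zinc-alpha-2-glycoprotein, at least 3.98-fold and NPEPL1 at least 2.75-fold lower. AURKB, the mitotic kinase aurora B, was 3.39-fold, PLEKHH1 3.25-fold and RLN1 3.22-fold lower. CNPY3 was at -1.85 on a probe not above background with EZH2 siRNA, so that size is not exact.

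Androgen targets were lower with EZH2 siRNA than with control siRNA. Of 36 measured androgen-induced genes, 19 were lower and 0 higher, with a median of -0.68 at percentile 0. KLK3 was lower by a log2 difference of -1.59 (bead SE 0.13), FKBP5 was 2.52-fold (-1.33, 0.11) and TMPRSS2 2.46-fold lower (-1.30, 0.08). Androgen-repressed genes were higher in 12 of 20 and lower in 2, with a median of 0.70 at percentile 100 that was 0.26 with bounds. Steroid and glucuronide genes, which share UGT2B members with that list, were higher in 7 of 14 and lower in 0 (0.80, or 0.38 with bounds). The LNCaP vehicle array was chosen as a comparison after the result was seen. Against it the EZH2 siRNA array had medians of 1.20 for androgen-induced, -0.77 for androgen-repressed and -0.09 for steroid genes. These directions were thus seen only against the control siRNA array. However, the vehicle culture is titled hormone deprived. Androgen-induced genes were higher on the control siRNA array too than on the vehicle array, in 33 of 36, and lower in 1. This swap therefore cannot decide whether the directions depend on the control siRNA array. Luminal markers were lower in 6 of 17 and higher in 1 (-0.40, percentile 0.07), the last being CD24, at least 2.93-fold higher. CD24 intensity was 5.4 with control siRNA, not above background, 173.3 with EZH2 siRNA, 865.2 with vehicle and 290.3 with R1881. Its higher value with EZH2 siRNA was thus seen only against the control siRNA array.

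Proliferation genes were lower with EZH2 siRNA than with control siRNA. Against the vehicle array the median over G1/S and G2/M genes was -0.01, with 3 genes higher and 4 lower. Lower proliferation genes too were thus seen only against the control siRNA array, and the vehicle array differs in treatment, so the swap cannot decide. Genes of G1/S and DNA replication had 14 of 29 lower and 0 higher (-0.56, percentile 0), led by CDC45, a replication fork factor (-1.59), DTL (-1.42), RRM2, a ribonucleotide reductase subunit (-1.40), and POLA1 (-1.32). Genes of G2/M had 14 of 28 lower and 0 higher (-0.58, or -0.56 with bounds, percentile 0), with AURKB, BIRC5, survivin (-1.27), and CCNA2, cyclin A2 (-0.98). Cell-cycle inhibitors and p53 targets were higher in 7 of 16 and lower in 0 (0.22, or 0.14 with bounds, percentile 95.2), with CDKN1A, p21, at 1.63, GADD45A at 1.53 and SESN1 at 1.14. Stress response genes were lower in 8 of 25 and higher in 1 (-0.44, percentile 0), including DNAJB9 (-1.19) and the chaperone HSPA5 (-0.90). Cholesterol and fatty acid genes were lower in 9 of 31 and higher in 0 (-0.23, percentile 0.24), including MSMO1 (-1.55). Interferon-stimulated genes were higher in 6 of 24 and lower in 1 (0.31, percentile 99.6, or 0.21 and within the central 95% with bounds), with IFITM3 at 1.22 and TAP1, a peptide transporter, at 1.11.

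Genes reported as repressed by EZH2 had 3 of 12 measured members at 1.5-fold higher and 0 lower with EZH2 siRNA, and their median of 0.07 lay at percentile 64.9. The higher members were CDKN1A, CDKN2B, at least 1.59-fold, and CDKN2A, whose bound of at least 1.47-fold does not show that it passed. Developmental factors bound by Polycomb had 4 of 19 higher and 1 lower (0.18, percentile 81.9), with HOXA10 at 1.36. PRC2 subunits had JARID2 higher (1.53) and EZH2 lower among 9 (-0.09, percentile 29.4). PRC1 subunits had 1 of 9 higher and 1 lower (-0.06, percentile 30.7). Neuroendocrine markers (0.56, or 0.36 with bounds, 2 of 4 higher and 0 lower, with TUBB3, a neuronal tubulin, at 1.63) and mesenchymal markers (0.64, or 0.42 with bounds, 2 of 4 higher and 0 lower, with VIM, vimentin, at 1.18) were few, both medians lay within the central 95% with bounds, and the mesenchymal median was -0.18 with a looser detection filter. Hypoxia genes (1 of 21 higher, 2 lower, -0.08) and housekeeping genes (0 of 24 higher, 1 lower, 0.03) lay within the central 95%.

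Among 11172 measured genes, 1172 were higher and 1093 lower with EZH2 siRNA. The higher share of 51.7% became 74.0% with median scaling (1901 higher, 667 lower), which moved the median of all measured genes from 0.04 to 0.18, so directions are relative to the scaling. With the vehicle array in place of the control siRNA array, 495 of the 1172 higher and 431 of the 1093 lower genes were called the same way. A second probe had the same sign for 418 of 454 genes and reached 1.5-fold the same way for 251 of them.

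**Figure D3:**
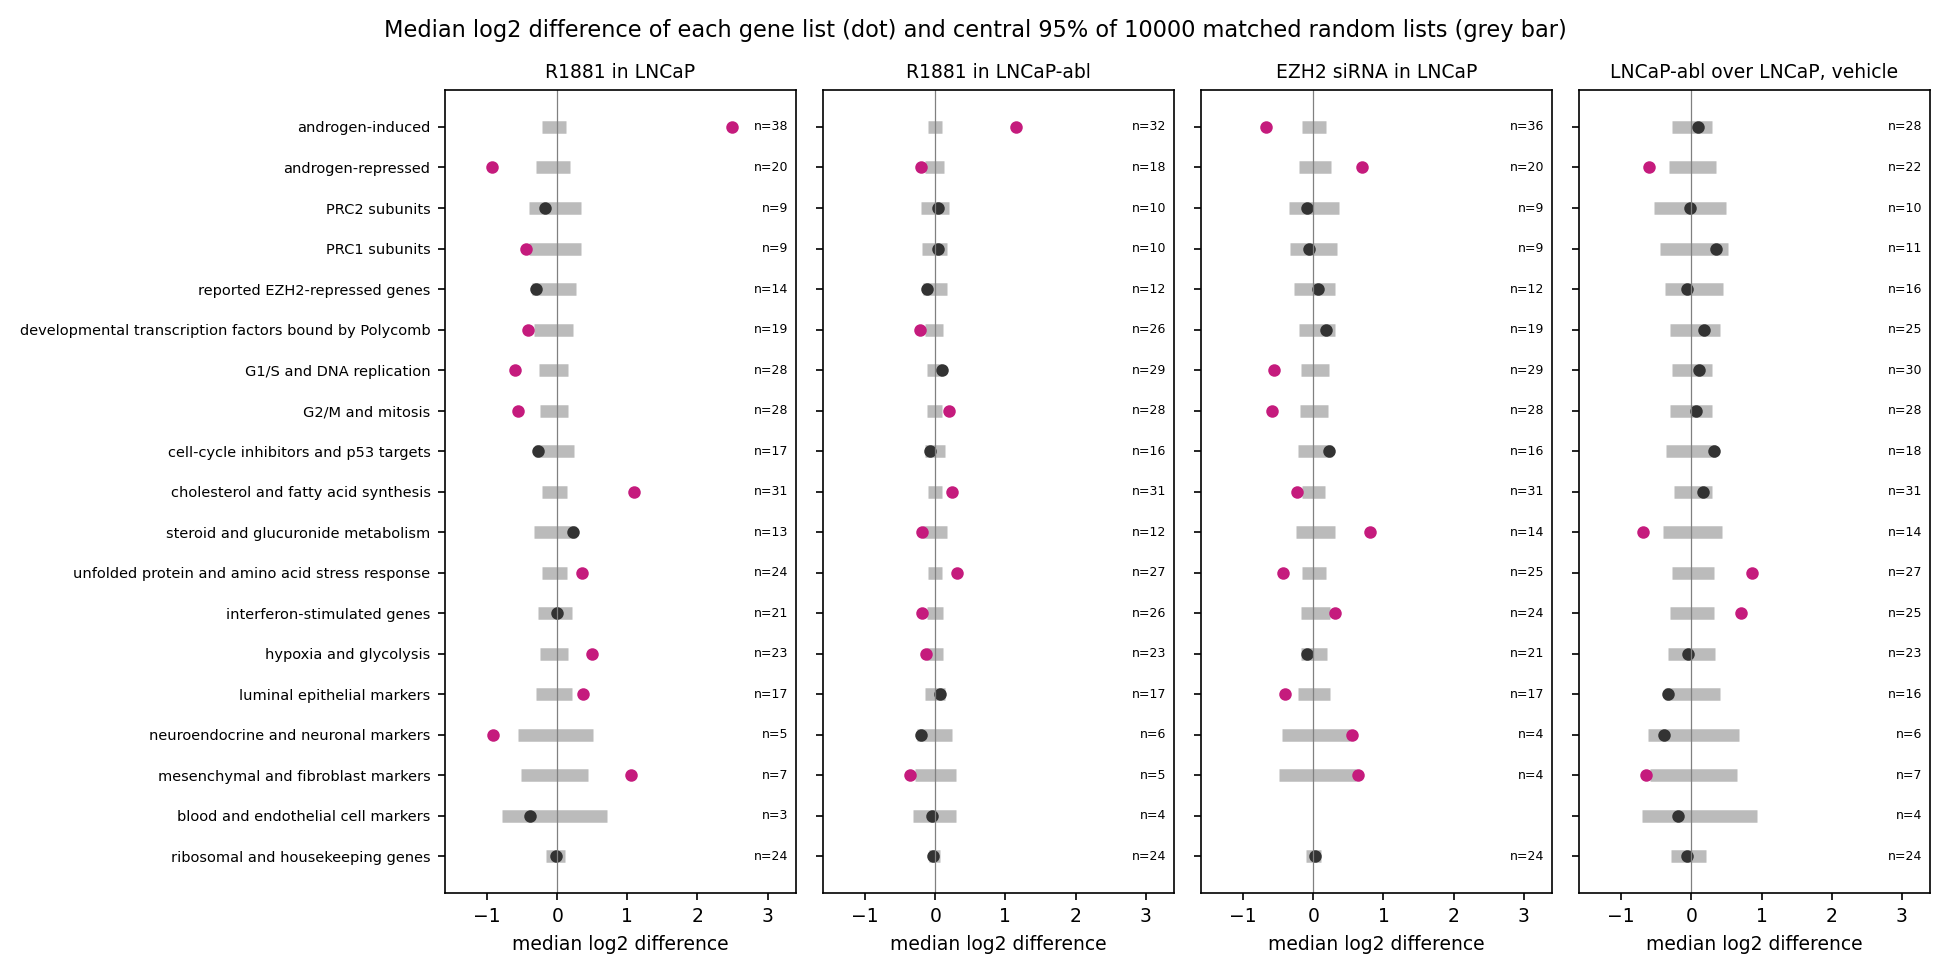
Median log2 difference of the measured members of each gene list (dots, with n members) in the 4 main comparisons, beside the central 95% of 10000 random lists matched on expression (grey bars). Pink dots lie outside that interval, among them the androgen-induced list at 2.49, 1.15 and -0.68 in the first 3 panels.

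Genes that differed with both R1881 and EZH2 siRNA in LNCaP mostly did so in opposite directions. Of 664 such genes among 10437 measured in both, 239 had the same sign. A set of 210 genes was lower with R1881 and higher with EZH2 siRNA, against 110 for independent lists and 103 to 142 in matched draws. Among them were UGT2B17 (-2.82 and 3.12), UGT2B15 (-2.22 and 3.48), BCHE (-4.32 and 1.47), TMEM144 (-1.83 and 1.40) and ATP1B1, a sodium pump subunit (-1.38 and 1.57). The reverse set held 215 genes, against 108 for independent lists and 95 to 132 in matched draws, and included KLK3, GNMT, TRIM51 (4.01 and -2.12), TM4SF1 (2.77 and -1.48) and HOMER2 (2.64 and -1.47). Genes higher in both numbered 108 against 106, with AGR2, a disulfide isomerase (3.54 and 1.87), and ID2 (2.82 and 1.74). Genes lower in both numbered 131 against 112, with RLN1 (-1.66 and -1.69) and RLN2 (-2.89 and -1.13). The correlation across genes was weak, with a Pearson coefficient of -0.143 and a Spearman coefficient of -0.095.

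The same comparison with the androgen response of LNCaP-abl, chosen after the result in LNCaP was seen and sharing no array or chip with the siRNA comparison, gave 144 genes past the threshold in both, of which 32 had the same sign. Genes higher with R1881 in LNCaP-abl and lower with EZH2 siRNA numbered 77 against 26.4 for independent lists and 18 to 37 in matched draws, and included SGK1 (2.73 and -1.35), FKBP5, TMPRSS2 and KLK4 (2.71 and -1.19). Genes lower with R1881 in LNCaP-abl and higher with EZH2 siRNA numbered 35 against 15.7, and 10 to 25 in matched draws. With the LNCaP vehicle array in place of the control siRNA array, the first of these sets held 30 genes against 43.2 for independent lists. Genes higher in both then numbered 119 against 38.7. The excess in the first set was thus seen only against the control siRNA array. The vehicle array differs in treatment too, so this swap cannot decide whether the control siRNA array stood apart.

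**Figure D4:**
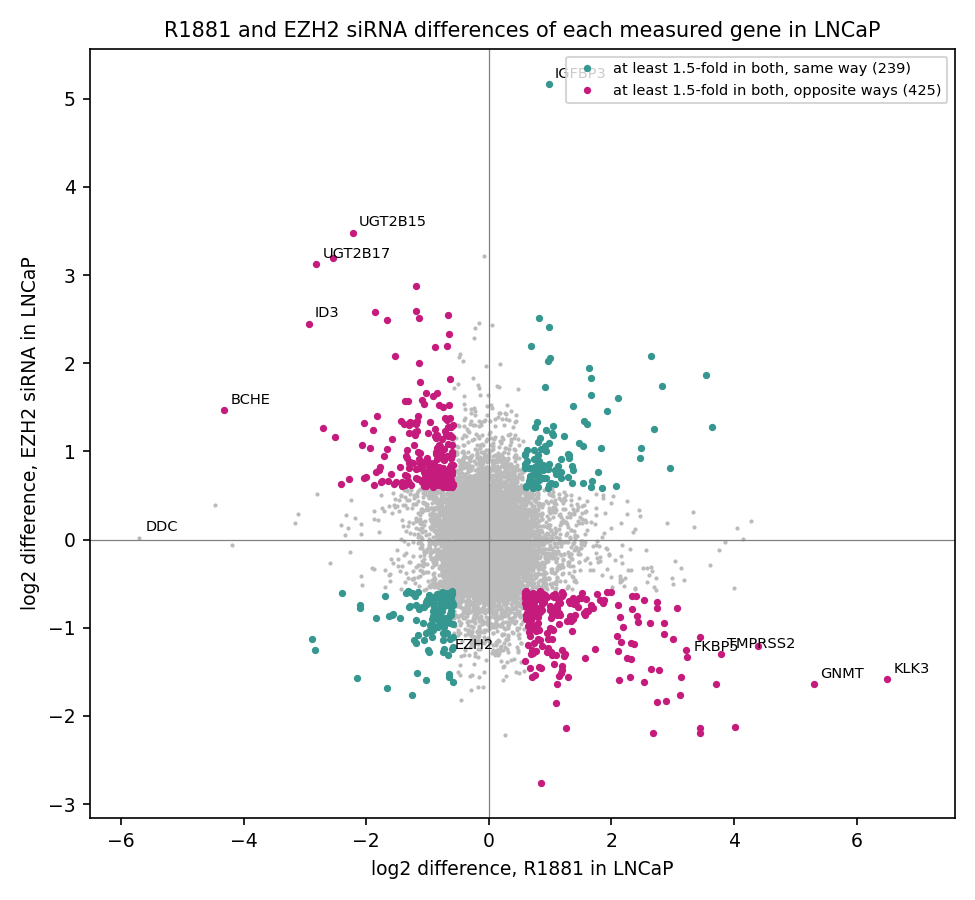
Each point is a gene measured in both comparisons in LNCaP, with its log2 difference with R1881 (horizontal axis) and with EZH2 siRNA (vertical axis). Pink points reached 1.5-fold in opposite ways and green points (239 genes) the same way. UGT2B15 and UGT2B17 lie at upper left and KLK3 at lower right.

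LNCaP-abl differed widely from LNCaP when both received vehicle. OR51E2, an odorant receptor gene expressed in prostate, was at least 156-fold higher, CHN1, a Rac GTPase-activating protein, at least 74.5-fold, PIGR, the polymeric immunoglobulin receptor, at least 73.5-fold and FEZ1 at least 49.6-fold higher. LCN2, lipocalin 2, was 131-fold higher (log2 7.03, bead SE 0.13), SDCBP2, syntenin 2, 97.8-fold, TSPAN8, a tetraspanin, 95.9-fold and the chemokine CCL20 77.9-fold. The amino acid transporter SLC7A5 was 67.6-fold higher and S100P was at a log2 difference of 5.70. Lower in LNCaP-abl were EEF1A2, an elongation factor, at least 179-fold, TMEFF2 at least 79.8-fold, NCAM2, a neural adhesion molecule, at least 78.2-fold and LDHB, lactate dehydrogenase B, at least 55.9-fold. TMSB10, an actin-binding thymosin, was 98.6-fold lower (-6.62, 0.16), TMEM205 49.3-fold, BCHE 43.4-fold and UGT2B15 36.9-fold. For BCHE and UGT2B15 the size depends on the LNCaP array used, here and where they are named below. The normalised log2 value of BCHE was 5.53 in LNCaP-abl with vehicle, 10.98 in LNCaP with vehicle and 7.57 in LNCaP with control siRNA. In LNCaP the intensity of UGT2B15 was far lower with control siRNA than with vehicle, as given above. TNFRSF19 was at least 43.1-fold and the histone variant gene MACROH2A2 at least 20.9-fold lower.

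Androgen-induced genes went both ways between the lines, with 10 of 28 higher and 10 lower in LNCaP-abl (median 0.09, percentile 69.5). TMPRSS2 was 4.61-fold higher (2.21, bead SE 0.12), whereas SORD, sorbitol dehydrogenase, was lower (-2.25). The normalised log2 value of TMPRSS2 was 9.97 in LNCaP-abl and 7.77 in LNCaP, both with vehicle. It was 11.30 in LNCaP with control siRNA, so its direction between lines depends on the LNCaP array used. EZH2 was at 0.15 (0.18) and FKBP5 at -0.42 (0.18), and KLK3 was not above background in either line. Androgen-repressed genes were lower in 11 of 22 and higher in 4 (-0.60, or -0.58 with bounds, percentile 0.01), and steroid genes lower in 8 of 14 and higher in 2 (-0.69, or -0.57 with bounds, percentile 0.12), with BCHE, UGT2B15 and UGT2B11 among the lowest of the former and UGT2B15 and UGT2B11 of the latter. Stress response genes were higher in 15 of 27 and lower in 1 (0.87, or 0.59 with bounds, percentile 100), with TRIB3 at 2.56, DNAJB9 at 2.32, ASNS, asparagine synthetase, at 2.01 and HERPUD1 at 1.78. Interferon-stimulated genes were higher in 15 of 25 and lower in 2 (0.71, percentile 100), with B2M, beta-2-microglobulin, at 1.35 and ISG15 at -1.66. Mesenchymal markers were lower in 4 of 7 and higher in 2 (-0.65, percentile 1.71, or -0.20 and within the central 95% with bounds), but their median was 1.13 over members detected on both arrays, with VIM at -1.46 and TAGLN, transgelin, at 1.99.

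Polycomb-bound developmental factors were higher in 11 of 25 and lower in 6 (0.18, or 0.07 with bounds, percentile 72.5), with FOXD1 at least 10.8-fold and HOXA13 at least 4.65-fold higher and ZIC2 at -2.70. EZH2-repressed genes were higher in 5 of 16 and lower in 5 (-0.07, or -0.10 with bounds, percentile 26.3), with CDKN1A at 1.92 and RUNX2 at least 2.86-fold higher. PRC2 subunits had 1 of 10 higher and 1 lower (-0.02), and PRC1 subunits 1 of 11 higher and 2 lower (0.35, or 0.22 with bounds). Medians within the central 95% were also found for genes of G1/S (0.11, 3 of 30 higher and 3 lower), G2/M (0.06, 3 of 28 higher and 4 lower), cell-cycle inhibitors (0.32, or 0.14 with bounds, 7 of 18 higher and 6 lower) and cholesterol synthesis (0.16, or 0.13 with bounds, 5 of 31 higher and 3 lower). So it was for hypoxia genes (-0.04, 6 of 23 higher and 6 lower, with VEGFA at 2.14), luminal markers (-0.33, 3 of 16 higher and 6 lower, with CD24 at -2.96) and neuroendocrine markers (-0.39, 2 of 6 higher and 3 lower). Blood markers (-0.20, or -0.07 with bounds, 0 of 4 higher and 1 lower) and housekeeping genes (-0.06, 5 of 24 higher and 2 lower) lay within it too. The normalised log2 value of CD24 was 6.852 in LNCaP-abl and 9.815 in LNCaP, both with vehicle. It was 4.904 in LNCaP with control siRNA, not above background, so its direction between lines depends on the LNCaP array used.

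Counts were 2529 higher and 2411 lower genes among 12384 measured, but line, chip and culture differed together, so these cannot be told apart. Of the higher genes, 1066 were at least 1.5-fold higher on both LNCaP-abl arrays than on all 4 LNCaP arrays, and 861 of the lower genes were lower on both. A second probe had the same sign for 939 of 1065 genes and reached 1.5-fold the same way for 663 of them.

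Genes higher with EZH2 siRNA were compared with the line difference, which used other arrays. Of 903 genes past the threshold in both, 468 had the same sign. Genes higher in both numbered 267 against 181 for independent lists and 155 to 199 in matched draws, led by IGFBP3 (5.17 and 4.66), TMSB4X (2.19 and 2.77) and S100A10 (1.94 and 5.28). Genes higher with the siRNA and lower in LNCaP-abl numbered 239 against 215, within the 200 to 249 of matched draws, but 59 against 25.5 for independent lists at a 2-fold threshold and 47 against 26.7 with the deposited log2 values. They included UGT2B15, UGT2B11 (2.51 and -4.46) and UGT2B7 (2.20 and -2.83). Across genes the Pearson coefficient was -0.001 and the Spearman coefficient 0.014.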

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

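Among the tests in this part, those of the 3 explanations for the opposite directions of the R1881 and siRNA differences, and that of a different androgen response of the cell lines, were chosen only after the results were seen. The weighing of small nucleolar RNAs as a class was also added after the result was seen, and it changed how that explanation was judged.

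A first group of results was singled out because the R1881 difference had opposite signs in the 2 cell lines, with 1 array per group, and the difference between lines was not tested. P4HA1, a collagen prolyl hydroxylase subunit, was at 0.88 (bead SE 0.08) in LNCaP and -0.70 (0.11) in LNCaP-abl. SDCBP2 was at 1.36 and -0.78, UGT2B7 at 0.69 and -0.69, and VWF at -2.83 and 0.88. VWF was not above background on the dimmer array in either line, and its bound of at least 1.16-fold in LNCaP-abl does not show a 1.5-fold difference there. In all, 19 genes, VWF included, reached 1.5-fold in opposite directions, against 251 in the same direction. By list, hypoxia and glycolysis had medians of 0.49 in LNCaP and -0.13 in LNCaP-abl, and mesenchymal markers 1.05 and -0.37, the latter pair depending on the detection filter. G2/M and mitosis genes had medians of -0.56 and 0.20.

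Cell-cycle genes were lower with R1881 in LNCaP, whereas in LNCaP-abl 0 of 28 G2/M genes and 1 of 29 G1/S genes passed 1.5-fold. Against the control siRNA array, the median over G1/S and G2/M genes on the R1881 array was -1.194, with 54 of 56 genes lower. The R1881 array was thus low against both controls. This cannot exclude an odd LNCaP vehicle array, because the control siRNA array differs in treatment. The vehicle array was itself lower than the control siRNA array in these genes, with a median of -0.65. The normalisation did not account for the contrast between lines. Under each of the 6 others tried, the G2/M median of the response difference was at least 0.445 and stayed above the central 95% of matched lists. A different androgen response of the lines remains a hypothesis. Its G2/M median was 0.764, but line, chip and culture cannot be told apart here.

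Genes that differed with R1881 and with EZH2 siRNA did so in opposite directions more often than matched draws. Direct release of androgen-repressed genes would not by itself give the set of 215 genes higher with R1881 and lower with the siRNA. That set was also above its draws, at 95 to 132. Whether released genes in turn lowered androgen-induced ones was not tested, and both sets rest on the same control siRNA array. Weaker androgen signalling on the EZH2 siRNA array than on the control siRNA array may contribute. Of genes higher with R1881 on the separate LNCaP-abl arrays, 77 were lower with EZH2 siRNA, above the 18 to 37 of matched draws. This set is not independent of the 215. Among genes measured with R1881 in both lines, 160 of the 279 higher in LNCaP-abl were also higher in LNCaP. That the control siRNA array alone stood apart stays open. With the vehicle array in its place, only 30 genes higher with R1881 in LNCaP-abl were lower, against 32 to 56 in matched draws. The vehicle array differs in treatment. An off-target or transfection effect was not tested, with 1 siRNA group.

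Small nucleolar and Cajal body RNAs stood among the highest genes with EZH2 siRNA. As a class, small nucleolar RNAs were not low on the control siRNA array, with a median of 0.342 above the mean of the LNCaP vehicle and R1881 arrays. A class median cannot show this for the few RNAs among the highest genes, and those arrays differ in treatment. A low control siRNA array is therefore not excluded for these few RNAs. Other small non-coding RNAs were higher too with EZH2 siRNA, with a median of 0.764 and 12 of 18 at least 1.5-fold higher, as more RNA without poly(A) in the labelled sample could give. The small nucleolar RNAs as a class, weighed only after that value was seen, had a median of 0.06 at percentile 21.4, with 18 of 85 higher and 8 lower. These values pull apart, so the explanation stays open.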

How the results depend on the processing

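The shifted version without background correction and the swaps of arrays were alternatives chosen after seeing the data. No paired analysis was possible because each group had 1 array, and leaving out a replicate was not possible for the same reason. The planned version without background correction on unshifted signals was not run, since negative signals have no log. Size thresholds do not enter list medians, so no list value was given for them, and normalisation within each BeadChip gave no comparison of lines. Among counts and the EZH2 difference, 50 values moved by over 1.5 times or beyond the bead error. Of list medians, 159 moved by over the SD of matched random lists, 7 reversed and 809 did neither. Of named gene differences, 983 moved beyond the bead error, none reversed and 2973 did neither. Cyclic loess, each BeadChip alone, the mean of detected probes, the looser detection filters and the bead error threshold moved no count beyond 1.5 times. Except where said, the cause was not tested.

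In the version without background correction fewer genes passed, as the constant added to lift each array above 0 shrinks ratios. Genes lower with R1881 in LNCaP then numbered 850, those in LNCaP-abl 193 higher and 157 lower, and those with EZH2 siRNA 658 higher and 668 lower. A larger response in either line was found for 1802 genes, 94 genes were lower with R1881 and higher with the siRNA, 128 higher with the siRNA and lower in LNCaP-abl, and 161 shared R1881's direction in both lines. An offset of 50, which also shrinks ratios, gave 826, then 189 and 154, 619 and 678, and 1675, 90 and 126 in that order. The deposited log2 values, which keep a background, gave an EZH2 difference of -0.60 and R1881 counts of 498 and 366 in LNCaP and 114 and 76 in LNCaP-abl. They gave 265 and 305 genes with EZH2 siRNA, 1156 and 1110 between lines, and 775, 30, 47 and 98 for the differences and overlaps. Median scaling gave 1901 higher and 667 lower genes with EZH2 siRNA.

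Requiring detection on every array, which leaves fewer genes, gave 692 genes higher with EZH2 siRNA, 1671 higher in LNCaP-abl, 1693 response differences, and overlaps of 117 and 129. A 2-fold threshold gave 501 and 384 genes with R1881 in LNCaP, 81 and 42 in LNCaP-abl, 283 and 261 with EZH2 siRNA, 1141 and 1102 between lines, 790 response differences, and overlaps of 41, 59 and 66. The overlap of genes lower with R1881 and higher with the siRNA was 1.79 to 5.64 times that of independent lists over the settings, and 1.91 as reported. That of genes higher with the siRNA and lower in LNCaP-abl was 1.03 to 2.35 times, 1.11 as reported, 2.32 at 2-fold (59 against 25.5) and 1.76 with the deposited log2 values (47 against 26.7), so it lay above independent lists in every setting and the size of the excess varied. With the control siRNA array as the LNCaP control, 1847 of 2529 higher and 1439 of 2411 lower genes of LNCaP-abl were called the same way, and 1743 and 1456 were with the R1881 arrays of both lines. With the vehicle array in place of the control siRNA array, 1901 genes were lower with EZH2 siRNA, and 495 of 1172 and 431 of 1093 were called as before.

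The list medians counted as reversed came with small lists or dim genes. Detection on every array gave mesenchymal markers 1.127 between lines, and detection at the looser p gave them -0.18 with EZH2 siRNA. Without a filter, Polycomb-bound developmental factors (0.009), neuroendocrine (0.052) and mesenchymal markers (-0.012) reversed with R1881 in LNCaP, and mesenchymal markers with R1881 in LNCaP-abl (0.088) and in the response difference (0.065). Signal over background limits these results, since 26.8% to 34.5% of probes were detected per array.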

Other observations

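The comparisons in this part were all chosen after the results were seen. The LNCaP vehicle and control siRNA arrays, which no comparison above set against each other, differed in androgen targets. KLK3 had an intensity of 5.7 on the vehicle array and 1751.0 on the control siRNA array, TMPRSS2 205.7 and 2611.2 and FKBP5 336.3 and 1759.3. Genes of G1/S and G2/M were lower on the vehicle array than on the control siRNA array, with 32 of 57 lower, 1 higher and a median of -0.65. Against the vehicle array the EZH2 siRNA array had a cell-cycle median of -0.01, with 3 genes higher and 4 lower. The lower cell-cycle genes with EZH2 siRNA were thus seen only against the control siRNA array. Because the vehicle array differs in treatment, this does not show which control stood apart. Androgen-induced genes were higher on the control siRNA array than on the vehicle array in 33 of 36 and lower in 1, and androgen-repressed genes were lower in 12 of 20 and higher in 4, with a median of -1.19. The control siRNA array was thus nearer to the R1881 array than to the vehicle array on a log scale in these androgen targets. Its labels name no R1881, but its title names no hormone deprivation either, whereas the vehicle culture is titled hormone deprived. These values therefore do not show that the control siRNA array was the odd one.

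Small RNAs also differed between lines. Small nucleolar RNAs were lower in LNCaP-abl than in LNCaP with vehicle in 29 of 68 and higher in 5, with a median of -0.48 at percentile 0. Other small non-coding RNAs were higher in 6 of 15 and lower in 0, with a median of 0.35 at percentile 94.6. With R1881 in LNCaP the medians were -0.25 and -0.35, with 8 of 63 and 5 of 14 lower, and in LNCaP-abl 0.06 and 0.03. Among the genes with opposite R1881 differences in the lines were S100A10, a calcium-binding family member (1.64 in LNCaP and -0.88 in LNCaP-abl), the fatty acid elongase ELOVL1 (1.19 and -0.76), the transcriptional repressor TRPS1 (-1.24 and 0.83), the mitotic kinesin KIFC1 (-0.72 and 0.63) and TMSB15A (-0.67 and 1.02). These 5 genes were picked from the 19 after their values were seen.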
